A study of Mus musculus with 16 samples.

How the data were processed

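RNA was sequenced from mouse microglia and astrocytes in 16 libraries, 8 of each cell type, with 2 libraries in each of 4 groups. The groups were wild type (WT), conditional knockout of Rack1 (CKO), an Alzheimer's disease model with intact Rack1 (AD WT) and that model with the knockout (AD CKO). Per the labels, total RNA was taken with TRIzol, amplified from 10 ng with SMART-Seq chemistry and read in pairs of 150 bases on a NovaSeq instrument. The deposited tables, 1 per cell type, hold expected counts per gene, that is estimated reads not scaled to a common total, with some reads shared between genes as fractions. Between 27% and 33.6% of the non-zero values in a library were fractional. The authors' notes name fastp, HISAT2, StringTie and the mouse build mm10, without versions or roles, and the annotation release and the counting step are not stated. All columns could be assigned to a group, a cell type and a replicate, and the replicate numbers were not treated as pairs.

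Total counts ran from 27741882 to 33933068 per microglia library and from 29615853 to 35851170 per astrocyte library. There were 55414 features in the microglia data and 56980 in the astrocyte data, of which 55405 were in both. GENCODE M21, an annotation of mm10, matched 52081 (94%) and 52073 (91.4%) of them by identifier and supplied coordinates and transcript lengths. Symbols are those of the deposited tables. Expected counts were rounded to whole numbers and tested in R 4.3.3 with edgeR 4.0.16. Each cell type was fitted alone, over its 8 libraries, after the filterByExpr filter and TMM normalisation, with robust quasi-likelihood F-tests, which are two-sided. This left 17318 genes tested in microglia and 20116 in astrocytes. The common biological coefficient of variation was 0.0678 and 0.0579. Per cell type 5 comparisons were made, namely CKO vs WT, AD WT vs WT, AD CKO vs AD WT, AD CKO vs CKO, and the interaction, which is the CKO effect in the AD model minus the CKO effect without it. P values were adjusted by Benjamini-Hochberg within each comparison, and genes with an adjusted p under 0.05 are said to have risen, fallen or changed. Values after ± are standard errors for log2 fold changes and standard deviations for CPM, which are counts scaled to a common library total with the TMM factors, with n = 2 per group.

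Gene groups were 39 lists. They were homeostatic microglia, disease-associated microglia, interferon response, inflammatory cytokines and NF-kB targets, phagocytosis and amyloid receptors, complement, antigen presentation, pan-reactive, A1 and A2 astrocyte genes, homeostatic astrocyte genes, cytosolic ribosomal proteins, translation factors, reported RACK1 binding partners, unfolded protein and integrated stress response, nuclear oxidative phosphorylation, mitochondrially encoded proteins, glycolysis, cholesterol synthesis, lipid handling, lysosome and autophagy, proliferation, immediate early and dissociation genes, apoptosis and p53 targets, AD model and amyloid genes, and trophic and astrocyte-microglia signalling. A further 13 lists held markers of microglia, astrocytes, neurons, oligodendrocytes, oligodendrocyte precursors, endothelial cells, mural cells, fibroblasts, ependymal and choroid cells, border macrophages and monocytes, lymphocytes, neutrophils and erythroid cells. Lists with at least 5 tested members were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01 between genes, adjusted over the lists within a comparison. Camera compares the members with all other genes. Each call was repeated with a correlation estimated from the data, and fry in limma gave a test of the members alone. A list is said to pass or not by camera. The median of a list is that of its members' log2 fold changes, given with members passing over all genes, and the count adjusted over the list alone is given where it differs. Some genes stand in several lists.

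Genes to be named were chosen by rule. For each comparison these were Rack1 and the 10 largest positive and 10 most negative log2 fold changes (5 and 5 for the interaction) among genes that passed, had a mean of at least 5 CPM over the libraries compared and had groups that did not overlap, leaving out clone-like and predicted names. To these the rule adds up to 4 members of each list with the smallest p that passed, and up to 4 members of each list that passed its own test. The non-overlap condition did not apply to the interaction. Genes named outside the rule are said to have been chosen after their values were seen. The groups, comparisons, lists, this rule and the alternatives not said to be added were fixed before the data were examined.

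Agreement between comparisons was measured as Pearson correlation of log2 differences across genes, beside 100 simulated draws in which no group differed. Genes are not independent replicates, so no p is given for such correlations. The alternatives were RLE size factors, DESeq2 1.42.0, limma-voom with quality weights, no filter on low counts, a filter of at least 1 CPM in 4 libraries, a fit on the compared groups alone, a replicate block, a log2 fold minimum of 1, estimated correlations in the list test, and leaving out each library in turn. Added after the data had been seen were fits without genes enriched in the other cell type (at least 2 times the CPM in its WT libraries), an astrocyte fit without the CKO libraries, and an offset for transcript length. For the length offset 2 definitions of length were tried. The longest transcript came first, and the APPRIS principal transcript was chosen after that result was seen, because genes such as Rack1 and the ribosomal protein genes have long retained-intron isoforms. Values under both are given. The offset was a loess curve with a span of 0.5 of each library's deviations on log2 length, and lengths were known for 99.8% of genes tested in microglia and 97.2% in astrocytes.

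The pipeline was tested on simulated data with the same sizes and spread, in which 50 genes were given each fold change. In the CKO vs WT step it recovered 36% of 1.25-fold, 58% of 2-fold and 84% of 4-fold changes in microglia, and 18%, 80% and 80% in astrocytes. It called at most 16 unchanged genes in any comparison. Folds against a group with no counts are lower bounds from a floor of 3 counts over the group, and floors cover counting error only. Fitted log2 fold changes of genes near 0 in a group depend on the prior count and are no bound. No sample was left out. Groups of 2 are too small for tests for outlying libraries, for splits of the samples or for exact tests between groups, so the adjusted p values rest on the spread pooled over all genes and groups by edgeR and limma.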

Results

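Microglia and astrocytes were profiled by RNA sequencing in mice that carried a conditional knockout of Rack1 in microglia, an Alzheimer's disease (AD) model, both or neither. Rack1 encodes a scaffold protein of the small ribosomal subunit that also binds protein kinases. The 4 groups were WT, CKO, AD WT and AD CKO, with n = 2 libraries per group in each cell type. The labels do not give the AD model, the Cre driver, the way the cells were isolated, or whether the libraries of a group came from different animals. If they came from 1 pool of RNA, the p values and standard errors below cover technical variation only and say nothing of other animals. Libraries of the same group correlated across genes at 0.985 or more in microglia and 0.9883 or more in astrocytes, where genes are not independent replicates. The first principal component held 36.5% of the variance in microglia and 44.2% in astrocytes, and in astrocytes it set the CKO libraries apart from all others.

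In the microglia libraries the microglial markers had the highest sum. It lay between 38633 and 57527 CPM, against 317 to 456 CPM for the astrocyte markers and 2212 to 8920 CPM for the oligodendrocyte markers, which were highest in CKO. The astrocyte libraries were more mixed. Their astrocyte markers summed to between 10533 and 23635 CPM, their oligodendrocyte markers to between 6559 and 20869 CPM, and their microglial markers to between 526 and 2373 CPM. In all 4 CKO and AD CKO astrocyte libraries the oligodendrocyte sum exceeded the astrocyte sum, and in all 4 WT and AD WT astrocyte libraries the astrocyte sum was the larger.

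Rack1 (ENSMUSG00000020372; mm10, chromosome 11, 48800332 to 48806434, plus strand, protein coding) fell in microglia with the knockout. It stood at 96.7 ± 2.05 CPM in WT and 41.2 ± 1.12 CPM in CKO microglia, a log2 fold change of −1.23 ± 0.06 (adjusted p = 2.73e-15). In the AD model it stood at 114 ± 1.33 CPM without and 47.5 ± 0.423 CPM with the knockout, a log2 fold change of −1.26 ± 0.06 (adjusted p = 2.04e-15). The size of the fall did not differ detectably between the backgrounds (interaction −0.03 ± 0.09, adjusted p = 0.867). Rack1 rose slightly with the AD model, by a log2 fold change of 0.24 ± 0.06 without the knockout and 0.21 ± 0.06 with it. The first of these calls was lost without AD WT replicate 2 (0.23), and the second without CKO replicate 1 (0.20), CKO replicate 2 (0.23) or AD CKO replicate 2 (0.20), with limma-voom (0.21), with the compared groups alone (0.20) and without astrocyte-enriched genes (0.19). In astrocytes Rack1 rose from 59.5 ± 2.25 CPM in WT to 99.1 ± 4.73 CPM in CKO (0.74 ± 0.06), and fell from 74.8 ± 2.59 CPM in AD WT to 54.0 ± 1.03 CPM in AD CKO (−0.47 ± 0.06). It rose there by 0.33 ± 0.06 from WT to AD WT and fell by 0.88 ± 0.06 from CKO to AD CKO, and its interaction was −1.21 ± 0.09. With an offset for transcript length the astrocyte CKO vs WT value was 1.04 by the longest and 0.43 by the principal transcript, and the AD CKO vs AD WT value was −0.57 and −0.26.

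**Figure D1:**
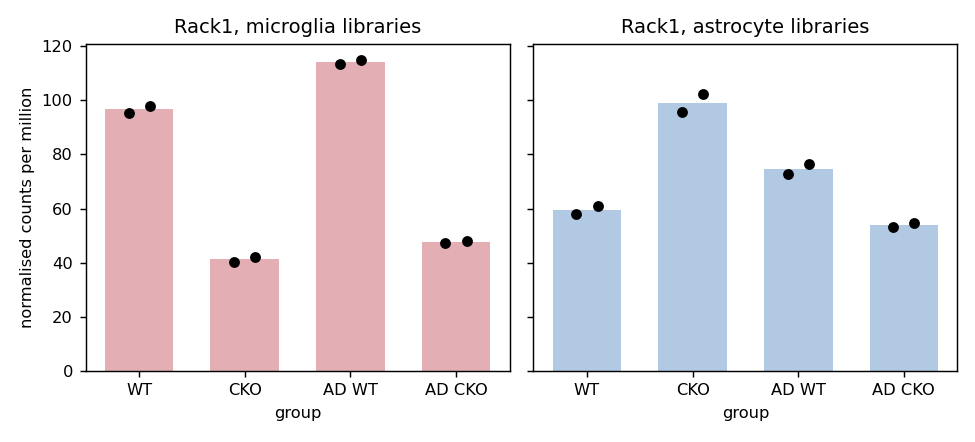
Normalised Rack1 counts in CPM (vertical axis) by group in microglia and astrocyte libraries, with points for libraries and bars for group means (n = 2 per group). Microglial Rack1 fell from a mean of 96.7 to 41.2 CPM with the knockout and from 114 to 47.5 CPM in the AD model, and astrocyte Rack1 was highest in CKO, at 99.1 CPM.

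CKO vs WT in microglia asked what the Rack1 knockout changed in microglia without the AD model. The interferon response rose, homeostatic microglia genes and immediate early genes fell, and the chemokine gene Cxcl13 had the largest rise among the genes named by rule. The calls of homeostatic microglia genes and of immediate early genes depended on the preset correlation (adjusted p = 0.0911 and 0.121 with an estimated correlation). Of 17318 genes tested, 3059 rose and 2756 fell (829 and 550 of them by at least 2-fold), and in 64.2% of all tested genes the groups did not overlap, against 33.3% by chance. Cxcl13 (ENSMUSG00000023078), whose product attracts B cells, went from 0.801 ± 0.175 to 553 ± 0.496 CPM (log2 fold change 9.43 ± 0.09, adjusted p = 2.77e-32). Gdf3, a ligand of the TGF-beta family, rose by 5.88 ± 0.14, and Cdkn1a, the cell cycle inhibitor p21, by 3.81 ± 0.06, from 32.7 ± 2.50 to 458 ± 29.4 CPM. The costimulatory receptor gene Cd40 rose by 3.74 ± 0.14 and Ms4a7, which is high in border macrophages, by 3.52 ± 0.07. Among the genes that fell were Gpr165, an orphan receptor gene (−3.52 ± 0.11), Ptger3, which encodes a prostaglandin E2 receptor (−3.50 ± 0.24), Mrc2, which encodes a collagen receptor (−3.07 ± 0.08), and Hpgd, which encodes a prostaglandin-degrading enzyme (−2.41 ± 0.05).

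In the same comparison all 20 interferon response genes rose, with a median of 1.34 (adjusted p = 3.32e-16), among them Oasl2 (2.48), Cxcl10 (2.07), Rtp4 (1.78) and Ifit3 (1.63). This was the only list of CKO vs WT microglia whose call held with an estimated correlation (adjusted p = 0.0274). Antigen presentation rose, with 11 of 14 genes up and 1 down (11 and 2 adjusted over the list alone), a median of 0.94 and H2-D1 at 1.70 and H2-K1 at 1.52 (adjusted p = 1.90e-05, but adjusted p = 0.136 with an estimated correlation). Homeostatic microglia genes fell, 14 of 15 of them, with a median of −0.76 (adjusted p = 1.22e-09, adjusted p = 0.0911 with an estimated correlation). They included Siglech (−1.96), Fcrls (−1.18) and Csf1r (−0.81). Disease-associated microglia genes split, 12 up and 9 down of 25, with a median of 0.08 (adjusted p = 0.648). Lyz2 (2.30) and Axl (1.69) rose in that list and Ccl6 (−1.89) fell.

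Immediate early and dissociation genes fell in CKO microglia, 17 of 19 with 1 up and a median of −1.08 (adjusted p = 6.02e-11, adjusted p = 0.121 with an estimated correlation), with Egr1 at −2.01, Atf3 at −1.77 and Klf2 at −1.23. Cytosolic ribosomal protein genes fell modestly, 45 of 75 with 2 up (50 and 2 adjusted over the list alone), with a median of −0.29 (adjusted p = 1.02e-09, adjusted p = 0.232 with an estimated correlation) and Rps3 at −0.53 and Rpl7 at −0.60. Translation factors went the same way, 15 of 33 down and 3 up with a median of −0.17 (adjusted p = 6.92e-04, adjusted p = 0.0911 with an estimated correlation), although Eif5 rose by 0.48. Nuclear oxidative phosphorylation genes fell, 22 of 34 (25 adjusted over the list alone), with a median of −0.26 and Ndufa9 at −0.60 (adjusted p = 2.29e-07, adjusted p = 0.125 with an estimated correlation). Cholesterol synthesis genes rose, 12 of 18 (13 adjusted over the list alone), with a median of 0.48 and Cyp51 at 1.06 (adjusted p = 1.17e-06, adjusted p = 0.0793 with an estimated correlation).

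Several lists did not pass the camera test against other genes in CKO microglia, although fry, which tests the members alone, passed and single members moved strongly. In the complement list, with 7 of 13 up and 3 down and a median of 0.15 (adjusted p = 0.119, by fry up with adjusted p = 6.08e-05), C3 rose by 3.12 and C5ar1 by 1.44. In the list of inflammatory cytokines and NF-kB targets, with 9 of 21 up and 5 down (9 and 6 adjusted over the list alone) and a median of 0.04 (adjusted p = 0.649, by fry up with adjusted p = 0.00745), Tnf rose by 1.24 and Il1rn by 1.39. Phagocytosis and amyloid receptors had 7 of 20 up and 6 down (7 and 7 adjusted over the list alone), a median of 0.03 (adjusted p = 0.894, by fry up with adjusted p = 0.00257), Tlr2 up by 1.60 and the inhibitory Fc receptor gene Fcgr2b down by 1.36. Reported RACK1 binding partners had 3 of 15 up and 4 down, a median of −0.03 (adjusted p = 0.454, by fry down with adjusted p = 0.0256) and Prkca, which encodes a protein kinase C, at −1.27. A2 astrocyte genes had 1 of 9 up and 4 down, a median of −0.44 (adjusted p = 0.183, by fry down with adjusted p = 0.00752) and S100a10 at −0.66, whose call was lost without CKO replicate 1 (−0.60). The lipid handling list passed narrowly, with 9 of 15 up and 3 down and a median of 0.44 (adjusted p = 0.0496, adjusted p = 0.162 with an estimated correlation), Apoe at 2.11 and the fatty acid receptor gene Cd36 at 1.56. Its call was also lost with RLE size factors (0.41), the filter of 1 CPM (0.32) and a replicate block (0.44), and without WT replicate 2 (0.45), CKO replicate 2 (0.39), AD WT replicate 1 (0.44), AD WT replicate 2 (0.44) or AD CKO replicate 2 (0.44).

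Markers of other cells moved in these libraries too. The summed markers of CKO relative to WT microglia were 2.69 times as high for oligodendrocytes, 2.37 for neurons, 2.60 for neutrophils and 2.39 for border macrophages, and 0.683 times as high for microglia and 0.451 for ependymal and choroid cells. The neutrophil list rose in all 7 genes with a median of 1.26 and Ngp at 1.59 (adjusted p = 1.79e-06, adjusted p = 0.0793 with an estimated correlation). Border macrophage markers rose in 6 of 9 genes (7 adjusted over the list alone) with a median of 0.44 and Ly6c2 at 1.62 (adjusted p = 9.48e-05, adjusted p = 0.0911 with an estimated correlation). Neuron markers rose in 7 of 12 genes (9 adjusted over the list alone) with a median of 1.19 and Snap25 at 1.51 (adjusted p = 8.11e-04, adjusted p = 0.0911 with an estimated correlation). The microglia markers fell in 8 of 10 genes with 1 up and a median of −0.31 (adjusted p = 2.85e-04, adjusted p = 0.11 with an estimated correlation), with Cx3cr1 at −1.14.

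**Figure D2:**
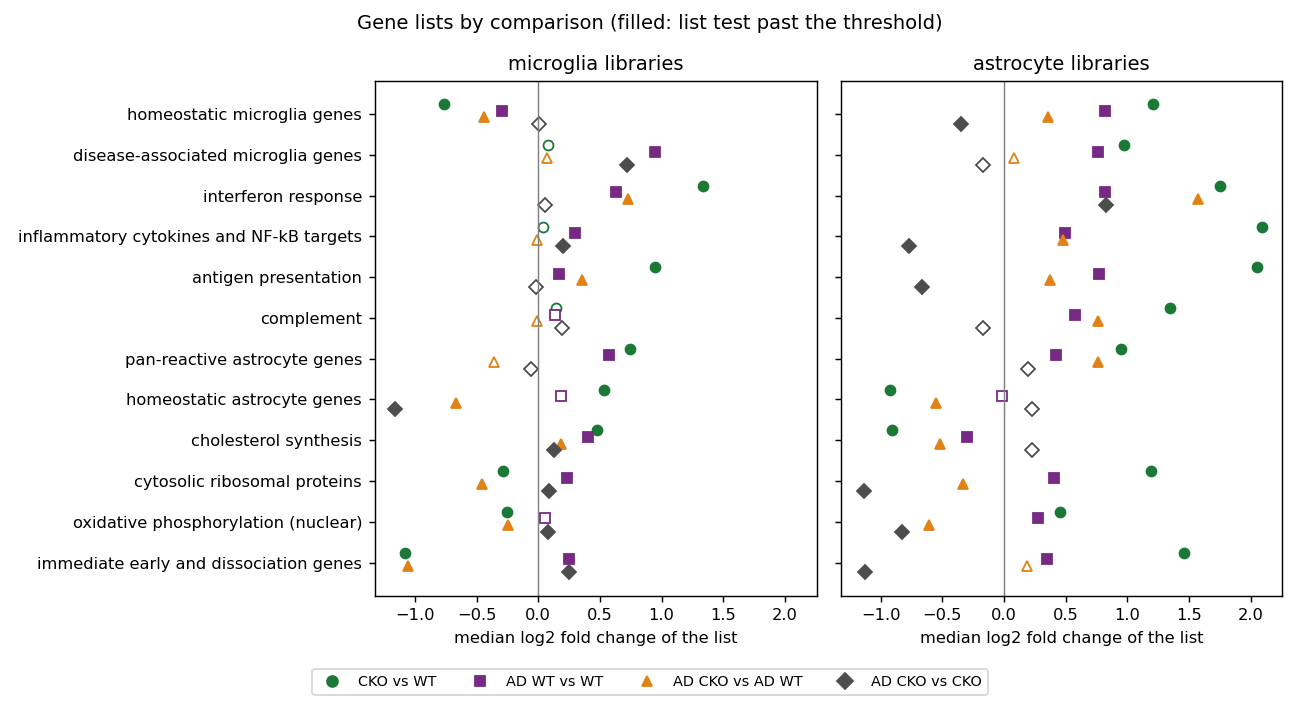
Median log2 fold change (horizontal axis) of 12 gene lists in the microglia and astrocyte libraries, with 1 symbol per comparison, filled where the camera test of the list passed at an adjusted p under 0.05. In CKO vs WT the interferon response was up in both cell types (medians 1.34 and 1.75), whereas homeostatic microglia genes lay at −0.76 in microglia and 1.21 in astrocyte libraries.

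AD WT vs WT in microglia asked what the AD model changed in microglia with intact Rack1. The disease-associated program rose throughout, interferon and lipid genes rose, and homeostatic genes fell a little. The call of the homeostatic genes depended on the preset correlation (adjusted p = 0.121 with an estimated correlation). Of the genes tested, 1851 rose and 1492 fell (391 and 112 of them by at least 2-fold), and groups did not overlap in 56.9% (33.3% by chance). All 25 disease-associated microglia genes rose, with a median of 0.94 (adjusted p = 3.63e-30, adjusted p = 0.0339 with an estimated correlation), among them Cst7 (2.00), Ank (1.84), Axl (1.77) and Lpl (1.70). Interferon response genes rose in 19 of 20 cases with a median of 0.63 and Oas1a at 1.07 (adjusted p = 2.62e-15, adjusted p = 0.0317 with an estimated correlation). Lipid handling rose, 9 of 15 up and 1 down, with a median of 0.53, Fabp5 at 1.62 and Apoe at 1.46 (adjusted p = 1.82e-06, adjusted p = 0.0365 with an estimated correlation), and so did cholesterol synthesis, 12 of 18 with a median of 0.40 (adjusted p = 5.95e-08, adjusted p = 0.0365 with an estimated correlation). Homeostatic microglia genes fell in 12 of 15 cases with 1 up and a median of −0.30, P2ry12 at −0.58 (adjusted p = 6.60e-06, adjusted p = 0.121 with an estimated correlation).

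In that comparison Igf1 rose by 1.89, Csf1 by 1.77 and Cxcl12 by 1.31, and the trophic and astrocyte-microglia signalling list had 6 of 15 up and 1 down (7 and 3 adjusted over the list alone) with a median of 0.30 (adjusted p = 0.00289, adjusted p = 0.116 with an estimated correlation). Proliferation genes rose, 8 of 18 (11 up and 2 down adjusted over the list alone), with a median of 0.37 and Cdk1 at 1.05 (adjusted p = 0.00302, adjusted p = 0.0908 with an estimated correlation). The glycolysis list rose, 13 of 17, with a median of 0.40 and Slc2a1, the gene of a glucose transporter, at 0.71 (adjusted p = 3.46e-08, adjusted p = 0.131 with an estimated correlation). The astrocyte gene Gfap had the largest rise named by rule, from 16.2 ± 0.743 to 113 ± 4.45 CPM (log2 fold change 2.81 ± 0.07), and the secreted Wnt modulator gene Dkk2 rose by 2.37 ± 0.20. The largest fall was in Tmem87a, at −2.41 ± 0.12. Markers of blood vessels rose as well, in all 9 endothelial genes with a median of 0.79 and Flt1 at 0.99 (adjusted p = 1.67e-09, adjusted p = 0.0339 with an estimated correlation) and in all 8 mural genes with a median of 0.62 and Acta2 at 0.63 (adjusted p = 1.82e-06, adjusted p = 0.0472 with an estimated correlation). The summed markers of AD WT were 0.878 times those of WT for microglia, 0.834 times for border macrophages and 0.726 times for ependymal and choroid cells. They were 1.24 times for astrocytes, 1.13 times for oligodendrocytes, 1.66 times for endothelial cells, 1.48 times for mural cells and 1.75 times for neutrophils. The neutrophil list rose in all 7 genes with a median of 0.83 (adjusted p = 3.67e-07, adjusted p = 0.0365 with an estimated correlation). The microglia markers fell in 6 of 10 genes with 2 up (7 and 2 adjusted over the list alone) and a median of −0.17 (adjusted p = 0.0294, adjusted p = 0.209 with an estimated correlation). That call was lost without WT replicate 2 (−0.19). The astrocyte markers passed narrowly, with 4 of 10 up and 1 down (5 and 1 adjusted over the list alone) and a median of 0.22 (adjusted p = 0.0496, adjusted p = 0.192 with an estimated correlation). This call was also lost with RLE size factors (0.22), the filter of 1 CPM (0.23) and a replicate block (0.22). It was lost without WT replicate 1 (0.16), CKO replicate 1 (0.23), CKO replicate 2 (0.22), AD WT replicate 1 (0.16) or AD WT replicate 2 (0.29). Fewer genes changed without AD WT replicate 1 or 2, where the library left alone is assumed to vary like the other groups.

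AD CKO vs AD WT in microglia asked what the Rack1 knockout changed in the AD model. Cxcl13 and the interferon response rose again, and ribosomal protein, homeostatic and immediate early genes fell. The calls of ribosomal protein, homeostatic and immediate early genes depended on the preset correlation (adjusted p = 0.174, 0.196 and 0.108 with an estimated correlation). There were 2941 genes up and 2601 down, but 431 up and 623 down by at least 2-fold. Groups did not overlap in 65.5% of genes (33.3% by chance). Cxcl13 rose from 1.28 ± 0.0644 to 350 ± 1.43 CPM (8.09 ± 0.08), Gdf3 by 6.31 ± 0.16, Cd40 by 3.62 ± 0.14 and Clec12a, an inhibitory lectin receptor gene, by 3.27 ± 0.09. The secreted synaptic protein gene Lgi2 fell (−4.54 ± 0.28), as did Tnfrsf17, a receptor gene best known from plasma cells (−2.22 ± 0.14). Interferon response genes rose in 19 of 20 cases with a median of 0.73 and Cxcl10 at 2.29 (adjusted p = 4.61e-13, adjusted p = 0.0444 with an estimated correlation). Immediate early genes fell in 18 of 19 cases with a median of −1.05 and Fos at −1.07 (adjusted p = 3.05e-13, adjusted p = 0.108 with an estimated correlation). Ribosomal protein genes fell in 62 of 75 cases (64 adjusted over the list alone) with a median of −0.46 (adjusted p = 1.76e-17, adjusted p = 0.174 with an estimated correlation). Homeostatic microglia genes fell in 10 of 15 cases with 3 up and a median of −0.44, Siglech at −1.35 (adjusted p = 2.45e-04, adjusted p = 0.196 with an estimated correlation).

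Disease-associated microglia genes did not pass as a list in AD CKO vs AD WT, with 11 of 25 up and 8 down (13 and 8 adjusted over the list alone) and a median of 0.07 (adjusted p = 0.38, by fry adjusted p = 0.0734). Lyz2 (1.67) and Spp1 (1.06) rose and Ank (−1.01) and Ccl6 (−1.35) fell. C3 rose by 2.42 and the scavenger receptor gene Msr1 by 1.77, and Csf1 fell by 0.81. Oligodendrocyte markers fell in all 9 genes with a median of −0.88 (adjusted p = 1.47e-06, adjusted p = 0.0732 with an estimated correlation), and homeostatic astrocyte genes fell in 12 of 15 (13 adjusted over the list alone) with a median of −0.67 and Slc1a2 at −1.22 (adjusted p = 5.88e-07, adjusted p = 0.0732 with an estimated correlation). Endothelial markers fell in 7 of 9 genes (8 adjusted over the list alone) with a median of −0.52 (adjusted p = 1.01e-04, adjusted p = 0.0875 with an estimated correlation). Mural markers fell in 7 of 8 (8 adjusted over the list alone) with a median of −0.64 (adjusted p = 1.60e-04, adjusted p = 0.108 with an estimated correlation). Neutrophil markers fell in 6 of 7 with a median of −0.56 (adjusted p = 0.00118, adjusted p = 0.108 with an estimated correlation). The microglia markers did not pass against other genes, with 2 of 10 up and 4 down and a median of −0.03 (adjusted p = 0.115, by fry down with adjusted p = 1.55e-04). The summed markers of AD CKO were 0.800 times those of AD WT for microglia, 0.609 times for oligodendrocytes and 0.730 times for astrocytes. They were 0.703 times for endothelial cells, 0.680 times for mural cells, 0.627 times for neutrophils, 1.13 times for ependymal and choroid cells and 2.09 times for border macrophages.

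AD CKO vs CKO in microglia asked what the AD model changed in microglia with the Rack1 knockout, in which Rack1 was reduced but still at 41.2 and 47.5 CPM. Disease-associated and lysosomal genes rose, while interferon genes did not pass against other genes. There were 1339 genes up and 1199 down, but 157 up and 526 down by at least 2-fold. Groups did not overlap in 52.7% of genes (33.3% by chance). Of 25 disease-associated microglia genes 22 rose, with a median of 0.72 (adjusted p = 1.32e-25, adjusted p = 0.0288 with an estimated correlation). Spp1, which encodes osteopontin, rose by 2.91 ± 0.05, the lipase gene Lpl from 82.3 ± 3.60 to 613 ± 17.4 CPM (2.90 ± 0.05), Cst7 by 2.25, Ank by 2.02 and the cholesterol hydroxylase gene Ch25h by 2.36 ± 0.10. Lysosome and autophagy genes rose in 14 of 22 cases (16 adjusted over the list alone) with a median of 0.24 and Hexa at 0.66 (adjusted p = 4.29e-09, adjusted p = 0.0408 with an estimated correlation). In AD WT vs WT that list had 13 of 22 up and 2 down (16 and 2 adjusted over the list alone) and a median of 0.19 (adjusted p = 1.22e-05, adjusted p = 0.0908 with an estimated correlation). Translation factors rose in 10 of 33 cases with 1 down (17 and 1 adjusted over the list alone) and a median of 0.13, Eif4a1 at 0.25 (adjusted p = 1.69e-05, adjusted p = 0.0303 with an estimated correlation). Interferon response genes had 4 of 20 up and 1 down (5 and 1 adjusted over the list alone) and a median of 0.06 (adjusted p = 0.0942, by fry up with adjusted p = 0.00717).

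Mitochondrially encoded protein genes fell in AD CKO vs CKO microglia, 9 of 13 (10 adjusted over the list alone), with a median of −0.53 and mt-Co1 at −0.59 (adjusted p = 8.27e-08, adjusted p = 0.108 with an estimated correlation). That list holds 1 gene with no counts in a group, and the median is the same with this gene at its bound. Mitochondrial genes took 1.43% and 1.33% of the counts in the CKO microglia libraries and between 0.871% and 0.999% in the other 6. In CKO vs WT microglia the same list rose, 7 of 13, with a median of 0.33 (adjusted p = 0.0212, adjusted p = 0.401 with an estimated correlation). That call was lost without WT replicate 2 (0.29) or CKO replicate 1 (0.30). Oligodendrocyte markers fell in 8 of 9 genes (9 adjusted over the list alone) with a median of −1.99, Mobp at −2.20 (adjusted p = 2.27e-11, adjusted p = 0.0288 with an estimated correlation), and neutrophil markers in 6 of 7 (7 adjusted over the list alone) with a median of −1.12, S100a9 at −1.18 (adjusted p = 4.29e-09, adjusted p = 0.0288 with an estimated correlation). The summed markers in AD CKO were 0.255 times those in CKO for oligodendrocytes, 0.409 times for neurons, 0.422 times for neutrophils and 1.82 times for ependymal and choroid cells. The Y-linked genes Ddx3y (8.47 ± 0.27) and Uty (7.86 ± 0.29) had the largest rises, with the knockout group near 0 CPM, so that these values depend on the prior count and are no bound.

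The interaction in microglia asked whether the knockout acted differently in the AD model. It was positive in 957 genes and negative in 1245, and at 2-fold or more positive in 112 and negative in 597. The rise of interferon genes with the knockout was smaller in the AD model, with 14 of 20 genes negative (15 adjusted over the list alone) and a median of −0.52, Oas1a at −1.20 and Oasl2 at −1.08 (adjusted p = 8.95e-10, adjusted p = 0.0242 with an estimated correlation). The fall of homeostatic microglia genes was also smaller, with 11 of 15 positive (12 adjusted over the list alone) and a median of 0.29 (adjusted p = 1.91e-07, adjusted p = 0.0837 with an estimated correlation). Among disease-associated genes Spp1 (1.42) and Lpl (1.19) gained and Axl (−1.36) and B2m (−0.68) lost, while the list had 5 of 25 positive and 11 negative (5 and 13 adjusted over the list alone) and a median of −0.13 (adjusted p = 0.0529). Apoe was at −1.37. Marker lists moved too, with medians of 0.21 for microglia (adjusted p = 4.79e-04, adjusted p = 0.0946 with an estimated correlation), −1.79 for oligodendrocytes, −1.94 for neutrophils and −1.16 for astrocytes (adjusted p = 0.0242 each with an estimated correlation) and −1.58 for neurons (adjusted p = 0.0447 with an estimated correlation). Without AD WT replicate 1 or 2 the number of genes with an interaction was 1457 or 1385, against 2202.

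Across all tested microglial genes the log2 differences of CKO vs WT and of AD CKO vs AD WT correlated at 0.426, against −0.004 in simulated data without group differences. Both comparisons changed 3473 genes, of which 3133 (90.2%) moved in the same direction. Genes up in both numbered 1736 where independence of the calls would give 519, and genes down in both 1397 against 414. AD WT vs WT and AD CKO vs AD WT share the AD WT libraries and correlated at −0.264, where simulation without group differences gave −0.507. Without AD WT replicate 1 or 2 it was −0.42 or −0.39, closer to that value, which was simulated with all libraries. The covariance was −0.087, against −0.0578 in the simulation. Genes up in the first and down in the second numbered 739 where independence of the calls would give 278, and genes down and then up 441 against 253. Those up in both numbered 447 against 314 and genes down in both 366 against 224. Shared libraries make opposite calls more frequent by construction, which the counts for independence leave out.

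**Figure D3:**
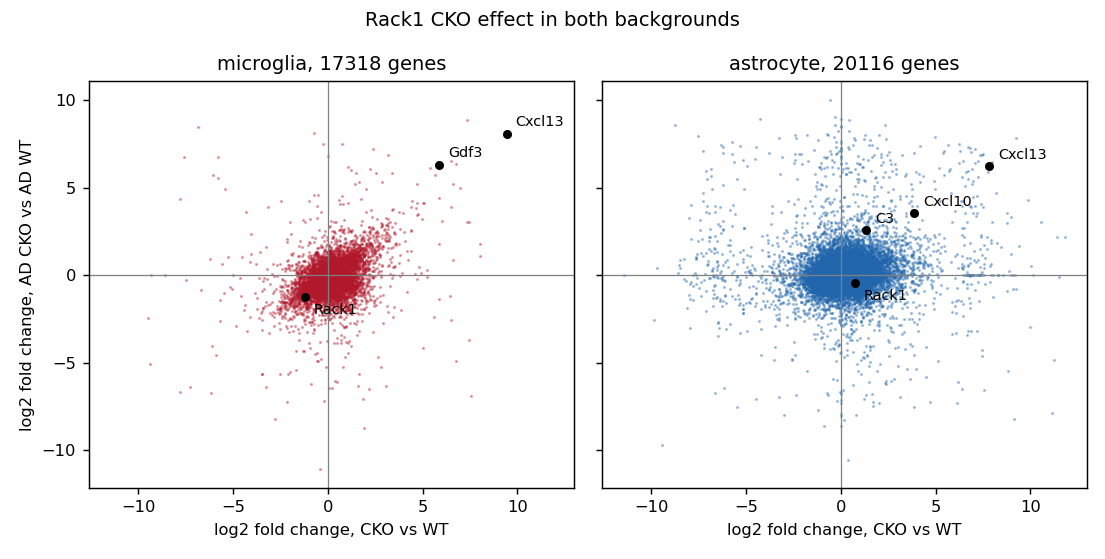
Log2 fold change of each tested gene for CKO vs WT (horizontal axis) and AD CKO vs AD WT (vertical axis) in microglia and in astrocytes, with 1 point per gene and a few named genes in black. The Pearson correlation across genes of the log2 differences was 0.426 in microglia and 0.124 in astrocytes.

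CKO vs WT in astrocytes asked whether the Rack1 knockout in microglia changed astrocytes without the AD model. Inflammatory, interferon, complement and immediate early genes rose, and astrocyte homeostatic and cholesterol synthesis genes fell. Astrocyte markers summed to 0.457 and microglial markers to 4.47 times WT, and a changed cell mixture was not separated from changes within astrocytes. No list kept its camera call with an estimated correlation (smallest adjusted p = 0.0577). Of 20116 genes tested 6354 rose and 6525 fell, but 2922 rose and 1946 fell by at least 2-fold. Groups did not overlap in 81.1% (33.3% by chance). The neutrophil chemokine gene Cxcl1 rose from 1.48 ± 0.216 to 122 ± 1.59 CPM (6.37 ± 0.11), the chemokine receptor gene Ackr1, known from venules, to 213 ± 7.43 CPM (7.42 ± 0.10), and the endothelial selectin gene Sele by 7.49 ± 0.24. Cxcl13 rose by 7.81 ± 0.26 here too, and Ch25h by 6.37 ± 0.11. The immunoglobulin genes Igkv6-15 (13.9 CPM in CKO) and Ighg1 (10.1 CPM) had no counts in WT and rose at least 282-fold and 205-fold, and Bpifa1, with 10.6 CPM in WT, fell at least 225-fold. Shisal1 fell by 3.66 ± 0.14.

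Inflammatory cytokines and NF-kB targets rose in 18 of 19 cases in CKO astrocytes with a median of 2.09 and Icam1 at 3.30 (adjusted p = 2.32e-08, adjusted p = 0.0735 with an estimated correlation). Immediate early and dissociation genes rose in 18 of 19 with a median of 1.45, Nr4a1 at 2.43 (adjusted p = 3.47e-09, adjusted p = 0.0577 with an estimated correlation). The interferon response rose in 19 of 20 with 1 down and a median of 1.75, Cxcl10 at 3.85 (adjusted p = 7.04e-08, adjusted p = 0.0577 with an estimated correlation), and complement in 12 of 13 with a median of 1.34, C1qb at 3.62 (adjusted p = 4.57e-06, adjusted p = 0.0577 with an estimated correlation). A1 astrocyte genes rose in 10 of 12 with 1 down and a median of 1.47, H2-T23 at 1.88 (adjusted p = 4.26e-05, adjusted p = 0.0577 with an estimated correlation). The acute phase gene Lcn2, a member of the pan-reactive list, rose by 4.13.

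Homeostatic astrocyte genes fell in 13 of 15 cases in CKO astrocytes with 2 up and a median of −0.92 (adjusted p = 4.26e-05, adjusted p = 0.0577 with an estimated correlation). They included the glutamate transporter gene Slc1a3 (−1.74), Aldh1l1 (−1.70) and the gap junction gene Gja1 (−1.43). All 18 cholesterol synthesis genes fell, with a median of −0.91 and Sqle at −1.27 (adjusted p = 7.38e-08, adjusted p = 0.125 with an estimated correlation). Vegfa fell by 1.60. Ribosomal protein genes rose in 74 of 75 cases (75 adjusted over the list alone) with a median of 1.19, Rps6 at 1.20 (adjusted p = 2.80e-15, adjusted p = 0.315 with an estimated correlation), and with the offset for transcript length the median was 0.59 by the longest and 0.50 by the principal transcript. Nuclear oxidative phosphorylation genes rose in 23 of 34 with 5 down (23 and 7 adjusted over the list alone) and a median of 0.45, Uqcrb at 1.08 (adjusted p = 0.00977, adjusted p = 0.549 with an estimated correlation), but the sign of this median turned to −0.12 with either offset for transcript length, and the call of Uqcrb was lost with that by the longest transcript (0.07). Log2 fold changes fell with the length of the longest transcript across 11556 genes in CKO vs WT astrocytes (Spearman −0.364, and −0.389 for the principal transcript). The other astrocyte comparisons had such trends as well, at −0.429 and −0.438 in AD WT vs WT, 0.323 and 0.339 in AD CKO vs AD WT, 0.459 and 0.495 in AD CKO vs CKO and 0.508 and 0.537 in the interaction. Mitochondrial genes took 4.3% and 4.39% of the counts in the CKO libraries and between 2.03% and 2.26% in the other astrocyte libraries.

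Markers of other cells rose in CKO astrocyte libraries. The summed microglial markers were 4.47 times those of WT, lymphocyte markers 8.62 times, border macrophage markers 3.87 times, endothelial markers 3.31 times and neutrophil markers 3.01 times, while astrocyte markers were 0.457 times and oligodendrocyte markers 0.983 times. All 10 microglia markers rose, with a median of 2.15 and C1qb again at 3.62 (adjusted p = 1.56e-06, adjusted p = 0.0577 with an estimated correlation). Lymphocyte markers rose in 8 of 9 with a median of 3.09 and the B cell gene Cd79a at 3.17 (adjusted p = 0.00204, adjusted p = 0.0884 with an estimated correlation), and the median is the same with the 2 genes that had no counts in a group at their bounds. Fibroblast markers had 5 of 6 up and 1 down and a median of 0.73 with no call for the list (adjusted p = 0.104), and Dcn rose by 1.00. Oligodendrocyte precursor markers had 3 of 8 up and 3 down, with a median of 0.06 and a list test in the opposite direction (adjusted p = 0.777), and Olig2 fell by 1.03.

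**Figure D4:**
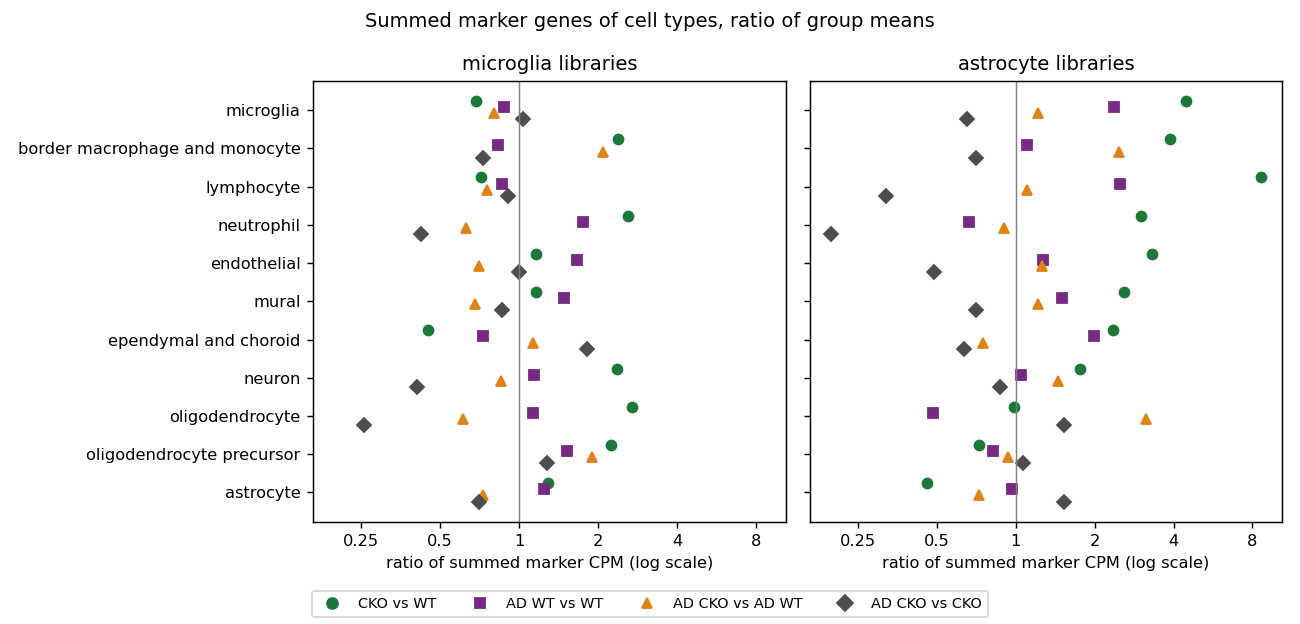
Ratio between group means of the summed marker CPM (horizontal axis, logarithmic) for 11 cell types in the microglia and astrocyte libraries, with 1 symbol per comparison and n = 2 libraries per group. In CKO vs WT astrocyte libraries the ratio was 4.47 for microglial markers and 0.457 for astrocyte markers.

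AD WT vs WT in astrocytes asked what the AD model changed in astrocyte libraries with intact Rack1. Complement, interferon and A1 genes rose together with microglial genes, and oligodendrocyte genes fell. There were 4023 genes up and 3625 down (934 and 737 of them by at least 2-fold), with non-overlapping groups in 69.2% of genes (33.3% by chance). The protease inhibitor gene Cst7, best known from reactive microglia, rose from 0.329 ± 0.0274 to 43.9 ± 1.00 CPM (7.05 ± 0.16), Tyrobp by 2.86 ± 0.09 and Trem2 by 2.60 ± 0.10. The complement list rose in 9 of 13 cases with a median of 0.57 and C3 at 1.93 (adjusted p = 5.14e-06, adjusted p = 0.0448 with an estimated correlation). A1 genes rose in 11 of 12 with a median of 0.58 (adjusted p = 4.57e-07) and interferon response genes in 16 of 20 with 1 down (16 and 2 adjusted over the list alone) and a median of 0.82 (adjusted p = 2.99e-06), each with adjusted p = 0.0448 with an estimated correlation. Gfap rose by 0.65. Homeostatic astrocyte genes did not pass against other genes, with 3 of 15 up, 4 down and a median of −0.02 (adjusted p = 0.498, by fry down with adjusted p = 0.0213), and Slc4a4 fell by 0.41.

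Microglial markers rose in all 10 cases in AD WT astrocyte libraries with a median of 0.99 and Ctss at 1.92 (adjusted p = 2.00e-08), and oligodendrocyte markers fell in all 9 with a median of −0.94 and Mbp at −1.26 (adjusted p = 2.79e-09), both calls with adjusted p = 0.0448 with an estimated correlation. As sums, microglial markers were 2.38 times and oligodendrocyte markers 0.482 times those of WT, and astrocyte markers 0.965 times. Endothelial markers were 1.27 times and ependymal and choroid markers 1.99 times. Ependymal and choroid markers rose in all 8 cases with a median of 0.70 and Folr1 at 0.96 (adjusted p = 9.46e-05, adjusted p = 0.146 with an estimated correlation), and all 5 erythroid genes rose with a median of 1.63, Hbb-bt at 1.67 (adjusted p = 2.94e-04, adjusted p = 0.265 with an estimated correlation). Cholesterol synthesis fell in 11 of 18 cases with a median of −0.30 (adjusted p = 1.00e-04, adjusted p = 0.268 with an estimated correlation). Xist rose by 9.47 ± 0.46 from 0.0155 CPM in WT, a value that depends on the prior count.

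AD CKO vs AD WT in astrocytes asked whether the Rack1 knockout in microglia changed astrocytes in the AD model. Interferon, complement and pan-reactive genes rose, and homeostatic, nuclear oxidative phosphorylation and cholesterol genes fell. Astrocyte markers summed to 0.723 times AD WT, and the cell mixture was again not separated. No list kept its camera call with an estimated correlation (smallest adjusted p = 0.0546). There were 5058 genes up and 5425 down, but 1591 up and 759 down by at least 2-fold. Groups did not overlap in 75.9% of genes (33.3% by chance). Cxcl10 rose from 8.91 ± 1.13 to 103 ± 1.96 CPM (3.54 ± 0.09) and C3 from 18.6 ± 0.213 to 112 ± 1.83 CPM (2.59 ± 0.07). All 20 interferon response genes rose with a median of 1.57, Oasl2 at 1.86 (adjusted p = 1.99e-11, adjusted p = 0.0546 with an estimated correlation). Pan-reactive astrocyte genes rose in 11 of 13 cases with a median of 0.76, Gfap at 1.33 and the oncostatin M receptor gene Osmr at 1.34 (adjusted p = 8.07e-06, adjusted p = 0.0864 with an estimated correlation), and complement in 11 of 13 with 1 down and a median of 0.76, C4b at 2.08 (adjusted p = 4.93e-05, adjusted p = 0.0905 with an estimated correlation). Homeostatic astrocyte genes fell in 14 of 15 cases with a median of −0.56, Gjb6 at −1.01 and Aldoc at −0.91 (adjusted p = 1.72e-06, adjusted p = 0.0864 with an estimated correlation). Nuclear oxidative phosphorylation genes fell in 32 of 34 (33 adjusted over the list alone) with a median of −0.61, Uqcrfs1 at −0.90 (adjusted p = 3.18e-10, adjusted p = 0.278 with an estimated correlation; −0.36 and −0.33 with the length offset by the longest and the principal transcript), and cholesterol synthesis genes in 16 of 18 (16 and 1 up adjusted over the list alone) with a median of −0.52, Fdft1 at −0.89 (adjusted p = 5.00e-05, adjusted p = 0.221 with an estimated correlation).

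Mitochondrially encoded protein genes had a median of −0.26 in AD CKO vs AD WT astrocytes (adjusted p = 0.0143, adjusted p = 0.357 with an estimated correlation), which turned to 0.05 and 0.04 with the length offsets. Oligodendrocyte markers rose in all 9 cases in AD CKO vs AD WT astrocytes with a median of 0.77 and Mobp at 2.23 (adjusted p = 1.72e-06, adjusted p = 0.107 with an estimated correlation), and their sum was 3.13 times that of AD WT. The summed astrocyte markers were 0.723 times, microglial markers 1.22 times, endothelial markers 1.26 times, mural markers 1.22 times, ependymal and choroid markers 0.751 times and border macrophage markers 2.48 times. The myelin-related gene Bcas1 rose by 2.65 ± 0.05 and the neuronal kinesin gene Kif5a by 3.07 ± 0.07. All 5 erythroid genes fell with a median of −2.27, Hba-a1 at −2.27 (adjusted p = 5.24e-04, adjusted p = 0.221 with an estimated correlation). Xist fell by 6.82 ± 0.34, to 0.124 ± 0.0618 CPM.

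AD CKO vs CKO in astrocytes asked what the AD model changed in astrocyte libraries of mice with the microglial knockout. Complement C3 and Gfap rose, and the inflammatory and immediate early genes that were high in CKO were lower. The calls of both lists depended on the preset correlation (adjusted p = 0.209 each with an estimated correlation). There were 6318 genes up and 5718 down (1692 and 1783 of them by at least 2-fold), with non-overlapping groups in 79.9% of genes (33.3% by chance). C3 rose from 12.4 ± 0.228 to 112 ± 1.83 CPM (3.18 ± 0.07), C4b by 1.83 and Gfap by 1.49, while Cxcl1 fell from 122 ± 1.59 to 3.04 ± 0.00196 CPM (−5.33 ± 0.09), and Ch25h (−4.04 ± 0.08) and Ackr1 (−3.48 ± 0.07) fell too. Inflammatory cytokines and NF-kB targets fell in 14 of 19 cases with 1 up and a median of −0.77, Nfkbia at −1.97 (adjusted p = 7.99e-05, adjusted p = 0.209 with an estimated correlation). Immediate early genes fell in 16 of 19 with a median of −1.13, Klf2 at −2.28 (adjusted p = 8.72e-08, adjusted p = 0.209 with an estimated correlation). Ribosomal protein genes fell in 73 of 75 with a median of −1.14 (adjusted p = 9.87e-18, adjusted p = 0.473 with an estimated correlation), and with the length offset the median was −0.50 by the longest and −0.37 by the principal transcript. Interferon response genes rose further, 12 of 20 with 2 down and a median of 0.82, Stat2 at 1.56 (adjusted p = 0.0148, adjusted p = 0.209 with an estimated correlation). The summed markers were 0.198 times those of CKO for neutrophils, 0.320 times for lymphocytes, 0.486 times for endothelial cells, 0.651 times for microglia, 0.635 times for ependymal and choroid cells, 1.53 times for astrocytes and 1.53 times for oligodendrocytes.

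The interaction in astrocytes asked whether the effect of the microglial knockout on astrocytes depended on the AD model. It was positive in 5940 genes and negative in 5690, and at 2-fold or more positive in 2575 and negative in 2736. Inflammatory cytokines and NF-kB targets were negative in 16 of 19 cases with a median of −1.87, Cxcl1 at −5.73 and Icam1 at −2.43 (adjusted p = 1.06e-05, adjusted p = 0.169 with an estimated correlation), and with the length offset the median was −1.20 by the longest and −1.29 by the principal transcript. The pan-reactive gene Lcn2 was at −3.37, and negative too were the microglial genes Trem2 (−3.40) and Tyrobp (−3.81). Complement C4b (1.71), Gfap (0.85), Osmr (1.49) and the transcription factor gene Stat2 (2.18) of interferon signalling were positive, while the interferon response list had 6 of 20 positive and 9 negative (6 and 10 adjusted over the list alone) and a median of −0.33 (adjusted p = 0.504). The astrocyte genes Slc1a3 (1.18) and Aldh1l1 (1.09) were positive. Marker lists had medians of −1.57 for microglia and 1.11 for oligodendrocytes (adjusted p = 0.169 each with an estimated correlation).

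Across tested astrocyte genes the log2 differences of CKO vs WT and AD CKO vs AD WT correlated at 0.124, against −0.002 in simulated data without group differences, and at 0.20 with the filter of 1 CPM. Of 7618 genes changed in both comparisons, 4228 (55.5%) moved in the same direction. Genes up in both numbered 1992 where independence would give 1597.7, and genes down in both 2236 against 1759.7. AD WT vs WT and AD CKO vs AD WT correlated at −0.437, where simulation gave −0.501. Their covariance was −0.256, against −0.0472 in the simulation. Genes up in the first and down in the second numbered 1862 where independence would give 1084.9, and genes down and then up 2046 against 911. Those up in both numbered 782 against 1011.5 and genes down in both 466 against 978. Here too, shared libraries raise the opposite calls by construction. Trends with transcript length were negative in CKO vs WT and AD WT vs WT but positive in AD CKO vs AD WT. Oligodendrocyte ratios differed too (0.983, 0.482 and 3.13). Their part in these agreements was not tested.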

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

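All tests of explanations in this part, the fits with an offset for transcript length among them, were chosen after the results had been seen. The results listed drew attention because an interaction test showed a difference between the AD and non-AD backgrounds, or because microglia and astrocytes moved in opposite directions.

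Y-linked genes held 4 of the 5 largest positive microglial interactions named by rule, with Ddx3y at 6.32, Uty at 5.59, Eif2s3y at 4.94 and Kdm5d at 3.13, fitted values that depend on the prior count because these genes were near 0 in CKO. Their summed CPM in replicates 1 and 2 was 20 and 14.9 in WT, 1.49 and 1.3 in CKO, 68.9 and 66.7 in AD WT, and 157 and 147 in AD CKO, while Xist was between 77.2 and 270 CPM in all 8. In astrocytes that sum was between 223 and 303 CPM in all 8, with Xist at 12.6 and 14.6 CPM in AD WT and at most 0.182 CPM in the others, so that Xist set AD WT apart there and the sex-linked genes differed between the cell types of a group. Animals of a single sex in each microglia library are argued against, since 6 had both Xist and the Y-linked sum at 5 CPM or more, and a different sex mixture is argued against as the cause of the microglial knockout changes shared by both backgrounds, since the Y-linked genes fell from WT to CKO and rose from AD WT to AD CKO whereas 90.2% of the genes changed in both comparisons moved in the same direction. Whether both libraries of a group were made from 1 pool of RNA cannot be told apart from similar mixtures of animals. The Y-linked sums of a pair differed by at most 1.34 times. With 1 pool, all p values and standard errors cover technical variation only. The sex of the animals stays open, as untested, for the other interactions and for the microglial comparisons of AD with non-AD groups. It stays open too for knockout changes not shared by both backgrounds and for the astrocyte comparisons with AD WT.

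Ribosomal protein genes in the CKO astrocyte libraries rose with a median of 1.19 (quartiles 1.01 and 1.39), and oxidative phosphorylation genes with a median of 0.45, in libraries where mitochondrial genes took 4.3% and 4.39% of the counts against 2.03% to 2.26% in the other astrocyte libraries. Whether a trend with transcript length was the whole cause of the ribosomal change could not be decided. With the preset correlation the list still passed after the offset. Its median was 0.59 by the longest transcript (quartiles 0.41 and 0.88) and 0.50 by the principal transcript (quartiles 0.37 and 0.70). But other protein-coding genes with short transcripts also rose. Their medians up to 600 bases were 1.12 by the longest and 0.97 by the principal transcript, and 0.85 and 0.74 from 600 to 1000 bases. The offset may correct such short transcripts too little. A trend with transcript length may account for the oxidative phosphorylation change, whose median went to −0.12 with both definitions. Ribosomal protein genes took at most 0.611% of counts in microglia libraries and at least 0.658% in CKO astrocyte libraries. Microglial RNA stays open, as a length trend could raise its 0.611%. An effect of the microglial knockout on astrocytes and a technical difference shared by both CKO libraries, in length or otherwise, stay open.

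Microglial and vascular genes rose together in the CKO astrocyte libraries, with all 10 microglial markers up and summed markers at 4.47 times WT for microglia and 3.31 times for endothelial cells. A lower share of astrocytes alone is argued against, because it would raise all other cell types alike, and the ratios for microglia and oligodendrocytes (0.983) lay 4.55 times apart. RNA from 1 constant share of microglia like those of the microglia CKO libraries is argued against as well, since the share needed by 173 microglia-enriched genes had quartiles of 1.22% and 4.57%, 3.76 times apart, with 0.504% for Csf1r, 1.92% for Cx3cr1, 8.48% for C1qb and 23.6% for Lyz2. Transcript length as the whole cause of the rise of microglial markers is argued against, since their median was 2.07 by the longest and 2.14 by the principal transcript, against 2.15 without the offset. RNA from macrophages or from microglia, with this or another profile, could contribute, and the labels name no sort that would remove them. An effect of the knockout on the tissue stays open too.

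Among single genes, the interaction tests also gave Tmem87a at 4.20 in microglia and Gnai1 at −2.58, Mapk8ip2 at −2.57, Ank3 at −2.56, Kif1a at −2.55 and Kif5a at −2.52, of 2202 genes past the threshold. In astrocytes 11630 genes passed, with Kif5a at 4.15, Shisal1 at 3.85, Kcna6 at 3.38, Tppp at 3.25, Erbb3 at 3.25, Ighg2c at −12.93, Tsix at −8.40, Cst7 at −6.32, Ackr1 at −6.28 and Ch25h at −5.97. The values of Ighg2c, Tsix and Cst7 rest on groups near 0 CPM and depend on the prior count.

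Of the gene lists, 19 passed the interaction test in microglia. Positive medians were 0.29 for homeostatic microglia genes, 0.09 for translation factors, 0.21 for microglia markers and 1.01 for ependymal and choroid markers. Negative medians were −0.52 for the interferon response, −0.34 for antigen presentation, −0.81 for pan-reactive, −0.45 for A1 and −1.35 for homeostatic astrocyte genes, −0.16 for ribosomal proteins, −0.56 for mitochondrially encoded proteins and −0.27 for cholesterol synthesis. Among marker lists they were −1.16 for astrocytes, −1.58 for neurons, −1.79 for oligodendrocytes, −0.77 for endothelial cells, −0.79 for mural cells, −0.52 for border macrophages and −1.94 for neutrophils. With an estimated correlation 7 of these calls held, those of the interferon response, homeostatic astrocyte genes and the markers of astrocytes, neurons, oligodendrocytes, endothelial cells and neutrophils. The call for translation factors was lost without AD WT replicate 2 (0.09) and with the filter of 1 CPM (0.08).

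In astrocytes 22 lists passed the interaction test and none of the calls held with an estimated correlation. Medians were −1.32 for homeostatic and −0.75 for disease-associated microglia genes, −1.87 for inflammatory cytokines and NF-kB targets, −1.46 for antigen presentation, −0.61 for A1 genes, −1.53 for ribosomal proteins, −0.52 for translation factors, 0.43 for RACK1 binding partners, −1.11 for oxidative phosphorylation, −1.18 for mitochondrially encoded proteins, 0.49 for cholesterol synthesis, −0.52 for lipid handling and −1.32 for immediate early genes. Among marker lists they were −1.57 for microglia, 0.52 for astrocytes, 1.11 for oligodendrocytes, −0.52 for endothelial cells, −1.21 for mural cells, −0.63 for ependymal and choroid cells, −1.94 for lymphocytes, −1.84 for neutrophils and −2.20 for erythroid cells. Some calls were lost without 1 library, namely A1 genes without WT replicate 2 (−0.49), RACK1 binding partners without WT replicate 2 (0.35), CKO replicate 1 (0.32) or AD CKO replicate 1 (0.45), and also with the filter of 1 CPM (0.39), ependymal markers without WT replicate 2 (−0.54), AD CKO replicate 1 (−0.66) or AD CKO replicate 2 (−0.56), and neutrophil markers without WT replicate 1 (−1.24), CKO replicate 1 (−1.42) or CKO replicate 2 (−1.31).

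With the offset for transcript length (longest, then principal transcript) astrocyte interaction calls were lost for mitochondrially encoded proteins (−0.12 and −0.20), RACK1 binding partners (0.35 and 0.25), ependymal markers (−0.56 and −0.25) and neutrophil markers (−0.98 and −1.04), and by the principal transcript alone for lipid handling (−0.46, and −0.43 by the longest) and astrocyte markers (0.21, and 0.26). Medians also moved by over 1.5 times by 1 or both definitions for ribosomal proteins (−0.61 and −0.49), oxidative phosphorylation (−0.26 and −0.21), translation factors (−0.38 and −0.21), inflammatory genes (−1.20 and −1.29), antigen presentation (−0.89 and −0.77), cholesterol synthesis (0.38 and 0.32), endothelial markers (−0.83 and −0.92) and erythroid markers (−1.03 and −1.11). In microglia the call of translation factors was lost (0.07 and 0.07).

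Opposite directions were seen in 24 list results and Rack1 but not tested between cell types. By sex-linked genes the cell types of a group came from different mixtures of animals. Rack1 in CKO vs WT stood at 0.74 in astrocytes and −1.23 in microglia. In AD CKO vs CKO it stood at −0.88 and 0.21, with the microglial call lost under the alternatives given above. In CKO vs WT the astrocyte and microglia medians were 1.21 and −0.76 for homeostatic microglia genes, −0.92 and 0.53 for homeostatic astrocyte genes, 1.19 and −0.29 for ribosomal proteins, 0.35 and −0.17 for translation factors, 0.45 and −0.26 for oxidative phosphorylation, −0.91 and 0.48 for cholesterol synthesis, 1.45 and −1.08 for immediate early genes, 2.15 and −0.31 for microglia markers, −1.03 and 0.70 for astrocyte markers and 0.97 and −0.58 for ependymal markers. None of these calls held with an estimated correlation in astrocytes or microglia, with adjusted p in the same order of 0.0577 and 0.0911, 0.0577 and 0.0911, 0.315 and 0.232, 0.186 and 0.0911, 0.549 and 0.125, 0.125 and 0.0793, 0.0577 and 0.121, 0.0577 and 0.11, 0.113 and 0.094, and 0.179 and 0.139. In AD WT vs WT they were 0.81 and −0.30 for homeostatic microglia genes, −0.30 and 0.40 for cholesterol synthesis, 0.99 and −0.17 for microglia markers and −0.53 and 0.83 for neutrophil markers, and with an estimated correlation adjusted p was 0.0448 and 0.121, 0.268 and 0.0365, 0.0448 and 0.209, and 0.318 and 0.0365, so that no list held in both. Without WT replicate 2 the calls were lost for microglia markers in microglia (−0.19) and for neutrophil markers in astrocytes (−0.43). With the length offset (longest, then principal transcript) the CKO vs WT astrocyte medians were 0.59 and 0.50 for ribosomal proteins, −0.12 and −0.12 for oxidative phosphorylation and 0.63 and 0.68 for ependymal markers, and the AD WT vs WT median of neutrophil markers was −0.92 and −0.90.

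In AD CKO vs AD WT the astrocyte and microglia medians were 0.36 and −0.44 for homeostatic microglia genes, −0.52 and 0.18 for cholesterol synthesis, 0.77 and −0.88 for oligodendrocyte markers and 0.25 and −0.52 for endothelial markers. None of these calls held with an estimated correlation, with adjusted p in the same order of 0.221 and 0.196, 0.221 and 0.108, 0.107 and 0.0732, and 0.215 and 0.0875. In AD CKO vs CKO they were −0.77 and 0.20 for inflammatory cytokines and NF-kB targets, −1.14 and 0.09 for ribosomal proteins, −0.43 and 0.13 for translation factors, −0.82 and 0.07 for oxidative phosphorylation, −1.13 and 0.25 for immediate early genes and 0.59 and −1.06 for astrocyte markers. With an estimated correlation adjusted p was 0.209 and 0.0735, 0.473 and 0.522, 0.209 and 0.0303, 0.437 and 0.456, 0.209 and 0.401, and 0.209 and 0.0303, so that only the microglial calls of translation factors and astrocyte markers held. In microglia the ribosomal call was lost without AD CKO replicate 2 (0.03), and the oxidative phosphorylation call without CKO replicate 1 (0.12), CKO replicate 2 (0.07) or AD CKO replicate 2 (0.07) and with the filter of 1 CPM (0.07). With the length offset the astrocyte medians in AD CKO vs CKO were −0.50 and −0.37 for ribosomal proteins, −0.32 and −0.21 for translation factors, −0.19 and −0.21 for oxidative phosphorylation and 0.30 and 0.27 for astrocyte markers, and in AD CKO vs AD WT the call of homeostatic microglia genes was lost (0.21 and 0.25). Groups of 2 libraries were too small for a test for outlying libraries.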

How the results depend on the processing

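The fits said above to be added were chosen after the data had been seen. Requiring a log2 fold change of at least 1 left 1379, 503, 1054, 683 and 709 genes in microglia and 4868, 1671, 2350, 3475 and 5311 in astrocytes (CKO vs WT, AD WT vs WT, AD CKO vs AD WT, AD CKO vs CKO and interaction), because fewer changes reach that size. With an estimated correlation in place of the preset one the lists that passed went from 20, 20, 16, 20 and 19 to 1, 8, 1, 9 and 7 in microglia and from 27, 20, 24, 15 and 22 to 0, 6, 0, 0 and 0 in astrocytes. That test has the 4 residual degrees of freedom of the fit, and of the lost calls 30 of 69 in microglia and 37 of 102 in astrocytes had an estimated correlation no higher than the preset one. Beside the counts of 0 from camera, 15, 10, 9 and 10 lists had an unadjusted p under 0.05 and 37, 35, 34 and 35 passed with fry. The filter of 1 CPM in 4 libraries moved the correlations of CKO vs WT with AD CKO vs AD WT to 0.56 in microglia and 0.20 in astrocytes and those of AD WT vs WT with AD CKO vs AD WT to −0.20 and −0.31, and the cause was not tested. Without astrocyte-enriched genes 1574 genes changed in microglia in AD CKO vs CKO and 999 had an interaction, where fewer genes were tested. Leaving out each library in turn gave between 2118 and 3355 genes in AD WT vs WT microglia (2180 and 2118 without AD WT replicate 1 and 2) and between 1385 and 1968 with an interaction (1457 and 1385), each fit having fewer samples and assuming that the library left alone varies like the other groups. Over the same fits the correlations ran from 0.36 to 0.37 and from −0.42 to −0.25 in microglia (−0.42 and −0.39 without AD WT replicate 1 and 2), and from 0.09 to 0.12 and from −0.50 to −0.43 in astrocytes. Other counts of changed genes stayed within 1.5 times the reported count under all other alternatives, among them RLE size factors, DESeq2, limma-voom and no filter. With the length offset 2 astrocyte lists changed sign by both definitions of length, oxidative phosphorylation in CKO vs WT (0.45 to −0.12 by the longest and −0.12 by the principal transcript) and mitochondrially encoded proteins in AD CKO vs AD WT (−0.26 to 0.05 and 0.04), because the offset lowers or raises short transcripts as a group. Of the list results that passed, 26 of 95 in microglia and 6 of 108 in astrocytes passed in the same direction under all alternatives run for lists, and all of the others failed with the estimated correlation. Those alternatives were RLE size factors, the filter of 1 CPM (which left 3 lymphocyte results untested), the replicate block, the estimated correlation, the length offsets and each library left out.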

Other observations

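The gene lists and their tests below were fixed before the data were examined, and no test was added after the results were seen. Targets of p53 were among the microglial genes that rose with the knockout. In AD CKO vs AD WT 8 of the 15 genes of the apoptosis and p53 list rose and 1 fell (9 and 1 adjusted over the list alone), with a median of 0.34 (adjusted p = 0.00388, adjusted p = 0.108 with an estimated correlation), and Cdkn1a was at 2.63, Trp53inp1 at 0.91, Bax at 0.86 and Mdm2 at 0.52. In CKO vs WT the same list had 9 genes up and 5 down and a median of 0.52 but did not pass against other genes (adjusted p = 0.0653, by fry up with adjusted p = 5.34e-05), with Cdkn1a at 3.81 and Bax at 0.95. The interaction of the list was −0.10 (adjusted p = 0.765), so the backgrounds were not shown to differ for the list, although Cdkn1a rose less in the AD model (interaction −1.18, adjusted p = 5.08e-10). In the unfolded protein and integrated stress response list, CKO vs WT gave 6 of 17 up and 5 down, a median of −0.03 where the mean (0.14) and the list test were positive (adjusted p = 0.815, by fry adjusted p = 0.00394), and a rise of the transcription factor gene Xbp1 by 1.06.

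In astrocytes, proliferation genes rose in AD CKO vs AD WT, 11 of 18 with 2 down and a median of 0.57 (adjusted p = 0.0143, adjusted p = 0.187 with an estimated correlation), with Mki67 at 4.18, Ccnb1 at 2.25 and Mcm6 at 0.90. The list of AD model and amyloid genes did not pass against other genes in CKO vs WT astrocytes, with 2 of 11 up, 7 down and a median of −0.29 (adjusted p = 0.0556, by fry down with adjusted p = 5.21e-06), although the prion protein gene Prnp fell by 0.94. App fell by 0.56 from WT to AD WT and rose by 0.67 from AD WT to AD CKO, with an interaction of 0.82.

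Replicates differed by more than counting error. Between the libraries of a group the chi-square per degree of freedom over genes ran from 3.63 to 6.41, where counting error alone would give 1. The differences between replicates 1 and 2 correlated between groups by −0.03 to 0.037 in microglia and 0.0051 to 0.048 in astrocytes, so no pairing by replicate number was seen across all genes together. A pairing in some genes is not excluded. A replicate block raised the calls in every comparison, in CKO vs WT microglia from 5815 to 6142 and in AD WT vs WT astrocytes from 7648 to 8911. Tmem87a in microglia averaged 31.6 CPM in WT, 7.07 in CKO, 5.92 in AD WT and 24.5 in AD CKO.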
